A study of Mus musculus with 36 samples.

How the data were processed

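The measurements were HA ChIP-seq peak lists from mouse embryonic stem cells stably carrying an empty PiggyBac vector, HA-tagged H4WT, H4K91R or H4K91Q. Per the labels' protocols, cells were fixed with paraformaldehyde, chromatin was sheared by sonication, the tagged histone was pulled down on anti-HA magnetic beads, and libraries were made with a NEBNext Ultra II kit. The series has 36 samples, and 4 of them entered the work, 1 library per group. Groups were taken from the sample titles. Lists for the other 32 samples (inputs, neural cells and knockout lines) were not used here.

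Peaks were called with MACS2 on the mm10 build, per the submitters' processing notes. The peak names show that each pulldown was called alone against the input of its own line. The aligner, the MACS2 version, the handling of duplicates and the q threshold are not given in the sources used here. Each deposited peak has a score, which equals 10 times its −log10 q rounded down in 100% of peaks. The authors' fold enrichment, a ratio to the background at the summit, was used to describe, rank and match regions within a list and never compared between lists. The −log10 p of the summit, as deposited by the authors, was not used. The authors' −log10 q served to filter peaks and to shorten lists. The lowest −log10 q in the deposited lists was 1.77 for the empty vector, 1.40 for H4WT, 1.58 for H4K91R and 1.40 for H4K91Q. The lists hold no read numbers, so depth is unknown. A deeper library lets the caller pass weaker places, so list lengths, and all shares that rest on them, can move with depth.

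Overlapping or adjoining peaks of a list were merged to regions, which removed 0 peaks in each list. Tagged regions overlapping an empty-vector region by at least 1 bp were left out after the first comparison. Overlaps between lists also needed at least 1 bp. Chance levels came from 100 seeded placements of each list on the same chromosomes with bedtools 2.31.1, and locally from shifts of 50 to 500 kb. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. With 1 library per group no test between groups was made and no p-value is given.

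Genes came from the RefSeq table of assembly GRCm38.p6, the same build as mm10. It holds 49997 genes, of which 49943 lie on the named chromosomes and 21887 are protein-coding. The table gives gene ends without strand or exons. The planned promoter window became a window of 1 kb on each side of both gene ends, and exons were not separated from introns. A region was placed by its midpoint: at a gene end, elsewhere in a gene, or outside. A gene was called marked where any region overlapped 1 of its windows. The planned sequence composition was not run, and random gene lists were not matched on CpG content, since no genome sequence was used here. Windows of 1 Mb were ordered by their protein-coding genes and divided into 5 equal groups, with ties divided in genome order.

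There were 18 gene lists: 12 of named symbols (pluripotency, neural progenitor, neuronal, mesoderm and endoderm, Hox, ribosomal protein, housekeeping, imprinted, 2-cell stage, germline, histone chaperone and H3.3, fibroblast) and 6 by symbol pattern (olfactory and vomeronasal receptors, clustered protocadherins, Zfp genes, replication-dependent histones, keratins). Of 445 symbols asked for, 439 matched the gene table. The gene lists, the main comparisons and the rule for named genes were fixed before the data were examined, with the departures given here. The rule took, per tagged library, the 10 marked genes of highest authors' fold, passing over predicted genes, then 10 marked by both mutants and not by H4WT and 10 marked by H4WT alone. For each list it took up to 3 members of highest H4WT fold and up to 3 marked by a mutant and not by H4WT. The 5 highest regions per list and class were named too. A few genes that the rule takes are not reported here. List members with an H4K91Q region beyond that rule were chosen after their values were seen.

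The number of marked genes in a list was set against 10000 random lists of the same size from all protein-coding genes. Lists from rotations of the gene order, lists matched on the decile of gene length (for regions anywhere in the gene or within 1 kb), and lists of H4WT-marked genes matched on the decile of H4WT fold were added after the data were seen. So was the share of each list, with its exact interval, beside that of all protein-coding genes under the same setting. Alternatives were a −log10 q of 5 or more, an overlap of 50% of each region, tagged lists cut to the 14314 peaks of highest −log10 q, empty-vector regions kept, windows of 500 bp and 2 kb, covered bases in place of regions, and, added later, the whole gene as window, all annotated genes, and H4WT lists shortened to the length or the number of marked genes of H4K91R. The overlap, location and gene-marking steps were tested on simulated regions: 100% of 5000 planted overlaps and 100% of 5000 planted gene-end regions were found, and 0% of 5000 regions placed in gaps were called overlapping. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.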

Results

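The series mapped where epitope-tagged histone H4 sits in the mouse genome. Cells carried a PiggyBac transgene for H4 with an HA tag, either wild type (H4WT) or with lysine 91 replaced by arginine (H4K91R) or by glutamine (H4K91Q), or an empty vector. HA ChIP-seq, which recovers DNA bound by the tagged histone, was done in embryonic stem cells, in their neural derivatives and in stem cells lacking Hira, DAXX or H3.3. Of the 36 samples, 18 were anti-HA pulldowns and 18 were inputs. Peak lists of 4 pulldowns were analysed here, all from otherwise unmodified embryonic stem cells: empty vector, H4WT, H4K91R and H4K91Q, with 1 library per group. The other 32 samples were not analysed here. The lists give no read numbers, so the depth of each library is unknown. No difference between libraries has a replicate check, and the exact 95% intervals below cover the counting of regions or genes only.

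The first comparison asked how much of the genome each tagged histone marked beyond the background of the pulldown. H4WT gave 69158 regions covering 24.0 Mb, H4K91R 49155 regions covering 16.6 Mb, and H4K91Q 14314 regions covering 6.13 Mb. The empty-vector line, which makes no tagged histone, gave 3007 regions covering 0.609 Mb. H4K91Q regions were the widest, with a median of 317 bp against 267 bp for H4WT, 271 bp for H4K91R and 174 bp for the empty vector. The narrowest region was 199 bp for H4K91Q, 189 bp for H4WT, 215 bp for H4K91R and 163 bp for the empty vector. The lowest width thus differed between lists, which limits a comparison of medians. Regions of at least 1 kb made up 5.41% of the H4K91Q list (exact 95% interval 5.04 to 5.79), 2.26% of the H4WT list (2.15 to 2.38) and 1.40% of the H4K91R list (1.30 to 1.51). Empty-vector regions were overlapped by 3.01% of H4WT regions (2.88 to 3.14), 2.56% of H4K91R regions (2.42 to 2.70) and 0.755% of H4K91Q regions (0.619 to 0.910). Seen from the empty vector, 70.0% of its regions met an H4WT region (68.4 to 71.7), 43.2% an H4K91R region (41.4 to 45.0) and 3.43% an H4K91Q region (2.80 to 4.14). These overlapping regions were left out of everything that follows, leaving 67078 regions for H4WT, 47898 for H4K91R and 14206 for H4K91Q. List length moves with sequencing depth as well as with occupancy, and only 853 empty-vector and 26265 H4K91R regions remained at a −log10 q of 5 or more.

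The second comparison asked whether the mutant histones sat where H4WT sat. The H4K91R list shared 54.0% of its regions with H4WT (53.5 to 54.4), 28.5 times the mean of 100 random placements. The H4K91Q list shared 18.8% of its regions with H4WT (18.2 to 19.5), 9.82 times the random mean, but 53.5% with H4K91R (52.7 to 54.3), 38.8 times the random mean. Against local shifts, which keep regions in the same neighbourhood, these ratios were lower, at 10.9, 7.36 and 26.7, so the mutants differed less in sharing with H4WT. From the other side, 37.7% of H4WT regions had an H4K91R region (37.4 to 38.1) and 4.09% an H4K91Q region (3.94 to 4.24). The 3 lists merged into 92820 places. H4WT alone held 41603 of them, H4WT with H4K91R 20939, H4K91R alone 16810, H4K91Q alone 6450 and the mutant pair without H4WT 4500. All 3 tagged histones met at 2389 places, and H4WT with H4K91Q but not H4K91R at 129.

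Regions in the top 20% by the authors' fold were shared more often than those in the lowest 20%. Among H4K91Q regions, 78.1% of the top 20% by fold overlapped H4K91R and 33.8% overlapped H4WT, against 43.6% and 13.8% of the lowest 20%, although the next 20% above the lowest had slightly less, 40.7% and 13.3%. Among H4WT regions, 66.8% of the top 20% and 23.3% of the lowest 20% had an H4K91R region. Lists of equal length, 14314 peaks each before empty-vector regions were removed, gave other shares: 6.92% of H4K91Q regions then met H4WT and 35.1% met H4K91R. In those lists 34.0% of H4K91R regions met H4K91Q (33.2 to 34.8) and 32.5% met H4WT (31.7 to 33.3). These shares were close, with slightly overlapping intervals, whereas the complete lists had 16.0% and 54.0%.

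**Figure D1:**
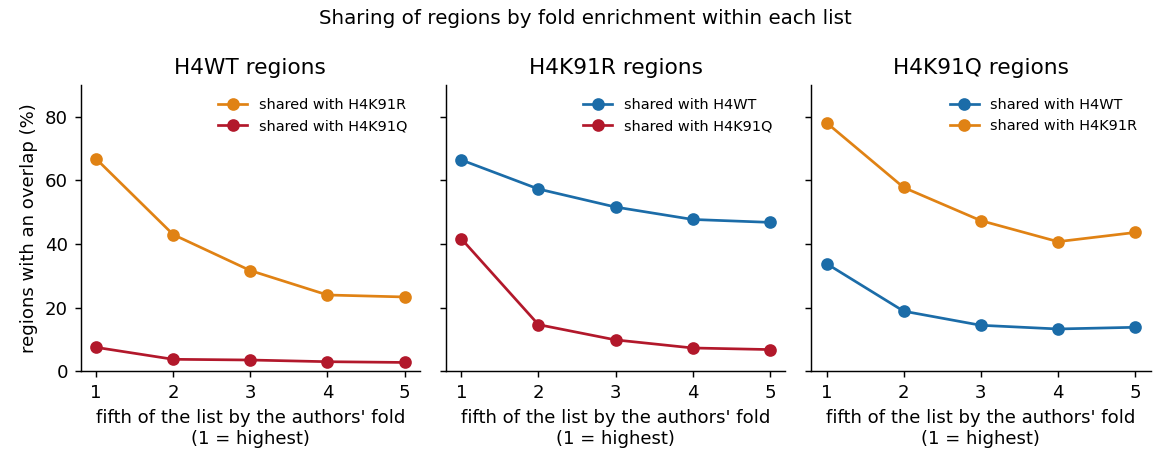
Percent of regions of each list (vertical axis) that overlapped a region of another list by at least 1 bp, in 5 equal groups of the list by the authors' fold enrichment (horizontal axis, 1 the highest), for H4WT, H4K91R and H4K91Q. In the top group of the H4K91Q list, 78.1% of regions were shared with H4K91R and 33.8% with H4WT.

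The strongest regions by the authors' fold showed the same sharing at single loci. In coordinates of mm10, the highest region of both the H4WT list (chromosome 10, 79737440 to 79741350, fold 33.5) and the H4K91R list (79736277 to 79742211, fold 57.8) lay inside Polrmt, the mitochondrial RNA polymerase gene. H4K91Q had a region of fold 23.5 there. A region inside Spred2, an inhibitor of Ras and MAP kinase signalling, was among the top 5 of all 3 lists (for H4K91Q, chromosome 11, 20017334 to 20022840, fold 24.8). The highest H4K91Q region lay inside Trak1, a kinesin adaptor gene (chromosome 9, 121328353 to 121329967, fold 27.5). Of H4K91Q regions shared with H4K91R and not with H4WT, the highest lay inside the integrin gene Itgb5 (chromosome 16, 33852499 to 33853623, fold 20.2), followed by a region 25747 bp from Mreg on chromosome 1 and regions inside Senp2, Tiam1 and Chn1. H4WT regions with neither mutant were led by regions at ends of Sppl2b, Timp2, Ddost and Polr2c. The region at Sppl2b spanned chromosome 10, 80855234 to 80856063, with a fold of 15.7.

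The next comparison asked where the regions lay relative to protein-coding genes. H4WT regions were concentrated at gene ends: 25.3% had their midpoint within 1 kb of either annotated end of a gene (24.9 to 25.6), 7.70 times the random mean of 3.28%. For H4K91R the share was 20.2% (19.8 to 20.6), 6.32 times random. For H4K91Q it was 2.20% (1.96 to 2.45), below its random mean of 3.01%. Outside genes lay 76.2% of H4K91Q regions (75.5 to 76.9), 37.8% of H4K91R regions (37.4 to 38.3) and 25.3% of H4WT regions (24.96 to 25.62), against 57.5% to 58.8% of randomly placed regions. Empty-vector regions lay mostly within genes, with 10.1% at gene ends, 58.3% elsewhere in genes and 31.6% outside.

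The places shared between lists divided in the same way. Of the places held by H4WT and H4K91R, 34.4% were at gene ends (33.7 to 35.0) and 3979 places lay outside genes. Of those held by H4K91R and H4K91Q without H4WT, 1.51% were at gene ends (1.18 to 1.91) and 77.3% outside genes. Even the places common to all 3 tagged histones were mostly outside genes, at 66.7% (64.8 to 68.6). H4K91R alone was intermediate, with 49.8% outside genes. In lists of equal length the share outside genes was 13.8% for H4WT and 43.0% for H4K91R, and the share at gene ends rose to 43.6% for H4WT. Gene starts and the other ends were not told apart.

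**Figure D2:**
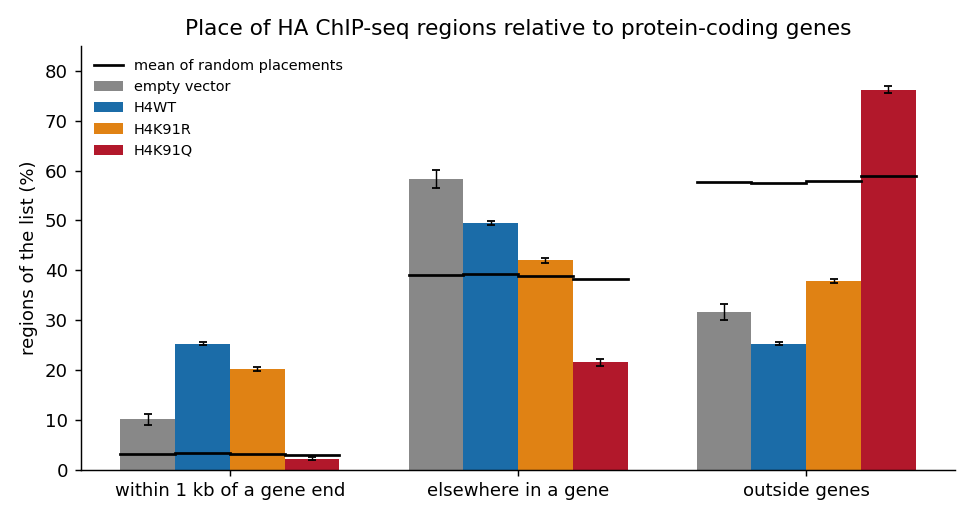
Percent of regions of each list (vertical axis) within 1 kb of an end of a protein-coding gene, elsewhere in a gene or outside genes, with exact 95% intervals as error bars and black lines for the mean of 100 random placements. H4K91Q regions lay outside genes in 76.2% of cases, above its random mean of 58.8%, and H4WT regions in 25.3%.

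Along the genome, H4WT followed gene density more closely than H4K91Q. The densest 20% of 1 Mb windows, with 13 to 67 protein-coding genes each, held 58.5% of H4WT regions (58.2 to 58.9), 48.5% of H4K91R regions (48.0 to 48.9) and 28.7% of H4K91Q regions (27.9 to 29.4). The sparsest 20%, with 0 to 1 genes, held 3.47%, 6.69% and 14.5%. Empty-vector regions followed gene density too, with 54.2% in the densest 20% (52.4 to 56.0) and 5.62% in the sparsest. The pattern of H4WT and H4K91R is thus not particular to tagged H4. Chromosome 11 had the most regions per Mb in the H4WT list, at 49.6, and in the H4K91R list, at 29.3. Chromosome 3 had the fewest H4WT regions per Mb among autosomes, at 13.5. Among autosomes H4K91Q ranged from 3.50 per Mb on chromosome 19 to 7.01 on chromosome 5. Chromosome X had 4.19 regions per Mb for H4WT, 3.61 for H4K91R and 1.26 for H4K91Q. Across the 19 autosomes, which are not independent replicates, Spearman's rho between genes per Mb and regions per Mb was 0.77 for H4WT, 0.74 for H4K91R and 0.07 for H4K91Q.

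**Figure D3:**
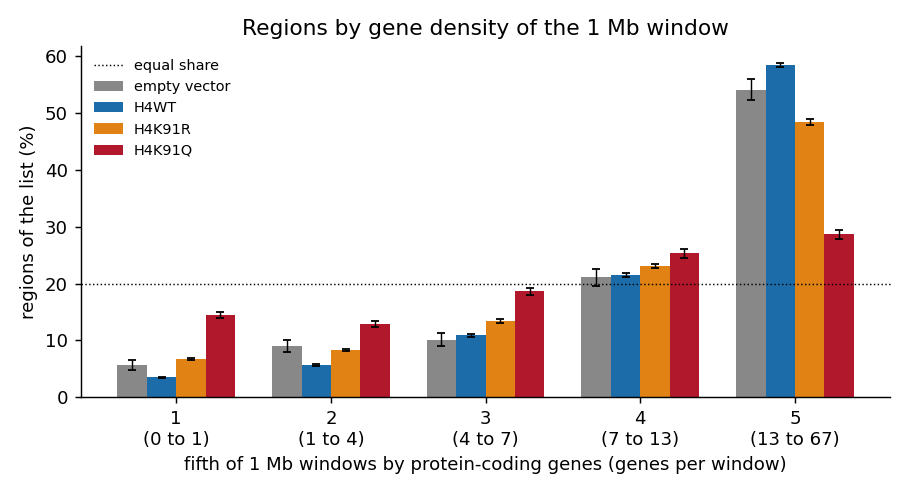
Percent of regions of each list (vertical axis) in 5 equal groups of 1 Mb windows ordered by their number of protein-coding genes (horizontal axis, range of genes per window in brackets), with exact 95% intervals as error bars and a dotted line at an equal share of 20%. The densest group held 58.5% of H4WT and 28.7% of H4K91Q regions.

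The following comparisons concerned genes with a region overlapping the 1 kb around either end, called marked here. H4WT marked 12775 of 21887 protein-coding genes, or 58.4% (57.7 to 59.0). H4K91R marked 8286 genes (37.9%, 37.2 to 38.5) and H4K91Q 277 genes (1.27%, 1.12 to 1.42). Empty-vector regions lay at the ends of 366 genes (1.67%). H4K91R marked 61.3% of the H4WT-marked genes, against 37.9% of all genes. Of the genes it marked, 94.5% were also marked by H4WT, against 58.4% of all genes. The lists can mark different ends of a gene, so these are not shares of common places. H4WT alone marked 4942 genes, H4WT with H4K91R 7615, and all 3 marked 213. Equal-length lists marked 29.2% of genes for H4WT and 13.9% for H4K91R.

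Several genes led more than 1 list by the authors' fold. Phyhipl, Zfp787 and Nnat (the imprinted neuronatin gene) were the top 3 marked genes of H4WT, and each also had H4K91R and H4K91Q regions. The H4WT region at Nnat spanned chromosome 2, 157559726 to 157561095, with a fold of 18.7. Irf2bpl, Asic4 (an acid-sensing ion channel), Chka (choline kinase) and Sarm1 (an NAD-cleaving enzyme of axon degeneration) came next, each with an H4K91R region and no H4K91Q region. In the H4K91R list the leading genes were Hcn2 and Polrmt, which share 1 region, Ezr and Sytl3, which share another, and the neighbours Elob and Srrm2. These 6 genes also led the H4K91Q list, with a region at Srrm2 and Elob on chromosome 17 from 23814553 to 23825667 and a fold of 24.6. H4K91Q was next highest at Rif1, a replication timing factor, Slc51a, and the imprinted gene Nap1l5.

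The mutant pair without H4WT marked 32 genes, led by Sytl3, Slc51a (a bile acid transporter subunit), Ube2l6 (an ISG15-conjugating enzyme), Abo (the blood group glycosyltransferase) and Zfp605. Of these, Slc51a had an H4K91R region at chromosome 16, 32488555 to 32489538, with a fold of 22.0. The H4K91R region at Sytl3 overlapped an H4WT region of fold 16.3 that did not reach the windows of Sytl3, so that place itself was shared. Pla2g4c, Pxt1, Lrif1, Zfp160 and Syt11 completed the first 10. Genes marked by H4WT alone were led by Cercam and Urm1, which share a region on chromosome 2 from 29845142 to 29846662 with a fold of 16.3. Next were Timp2 (an inhibitor of matrix metalloproteinases), Ddost (a subunit of the oligosaccharyltransferase), Icosl, Clic4, Rnf10, Wdr83os, Snx15 and Adra1b (an adrenergic receptor).

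Developmental regulators were among the most completely marked groups for both H4WT and H4K91R. Of 36 neural progenitor genes, H4WT marked 33 and H4K91R 32, and 0.01% and 0% of 10000 random lists of that size held as many. Zic2, Sox1 and Lhx2, transcription factors of early neural tissue, had the highest H4WT folds, at 13.1, 12.9 and 12.7. Hox genes, which pattern the body axis, were marked at 38 of 39 by H4WT and at 33 by H4K91R. Hoxa3, Hoxc12 and Hoxa4 led them, and Hoxa4 had no H4K91R region. Of 36 mesoderm and endoderm genes, H4WT marked 29 and H4K91R 28, with Foxc2, Cdx1 and Foxc1 the highest for H4WT and Myf5, a muscle determination factor, marked by H4K91R and not by H4WT. H4K91Q marked 1 neural progenitor gene, Pou3f2 (region at chromosome 4, 22487768 to 22487989, fold 4.11), no Hox gene and no mesoderm or endoderm gene. Random lists also held none in 61.8% for the size of the Hox list and 62.4% for that of the mesoderm and endoderm list.

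Pluripotency and neuronal genes were marked less completely. Of 32 pluripotency genes, H4WT marked 23, with 8.20% of random lists holding as many, and H4K91R marked 20, with 0.30% holding as many. Klf2, Sox2 and Utf1 had the highest H4WT folds. Tcl1 was marked by H4K91R and not by H4WT, and Tet2, a methylcytosine dioxygenase, was the 1 member marked by H4K91Q. Of 36 neuronal genes, H4WT marked 26 and H4K91R 19, with 6.05% and 4.77% of random lists holding as many. Neurod2, Slc17a7 (a vesicular glutamate transporter) and Grin1 (an NMDA receptor subunit) led the H4WT list, and Nefm, a neurofilament gene, was the 1 member with an H4K91Q region. Among genes with an H4WT region of like fold, H4K91R was present at more neural progenitor genes (32 of 33 against a median of 24 in matched random lists) and more mesoderm and endoderm genes (27 of 29 against 20). Of the marked pluripotency genes it was present at 19 of 23, against 13, and of the neuronal genes at 19 of 26, against 17, with 21.7% of matched lists as high. The H4K91R excess at pluripotency genes did not hold in shorter lists or narrower windows. At a −log10 q of 5 or more it marked 8 of them (25%, against 24.8% of all genes), and at equal length 4 (12.5%, against 13.9%). Windows of 500 bp gave 13, with the share of all genes inside the exact interval. At a −log10 q of 5 or more H4K91R marked 18 mesoderm and endoderm genes (50%, 32.9 to 67.1), above the share of all genes. H4K91R was also above it at neuronal genes in shorter lists, with 15 (41.7%) at a −log10 q of 5 or more and 11 (30.6%, against 13.9%) at equal length. The lists of equal length held 10 pluripotency genes for H4WT, and 26 and 21 neural progenitor genes for H4WT and H4K91R.

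**Figure D4:**
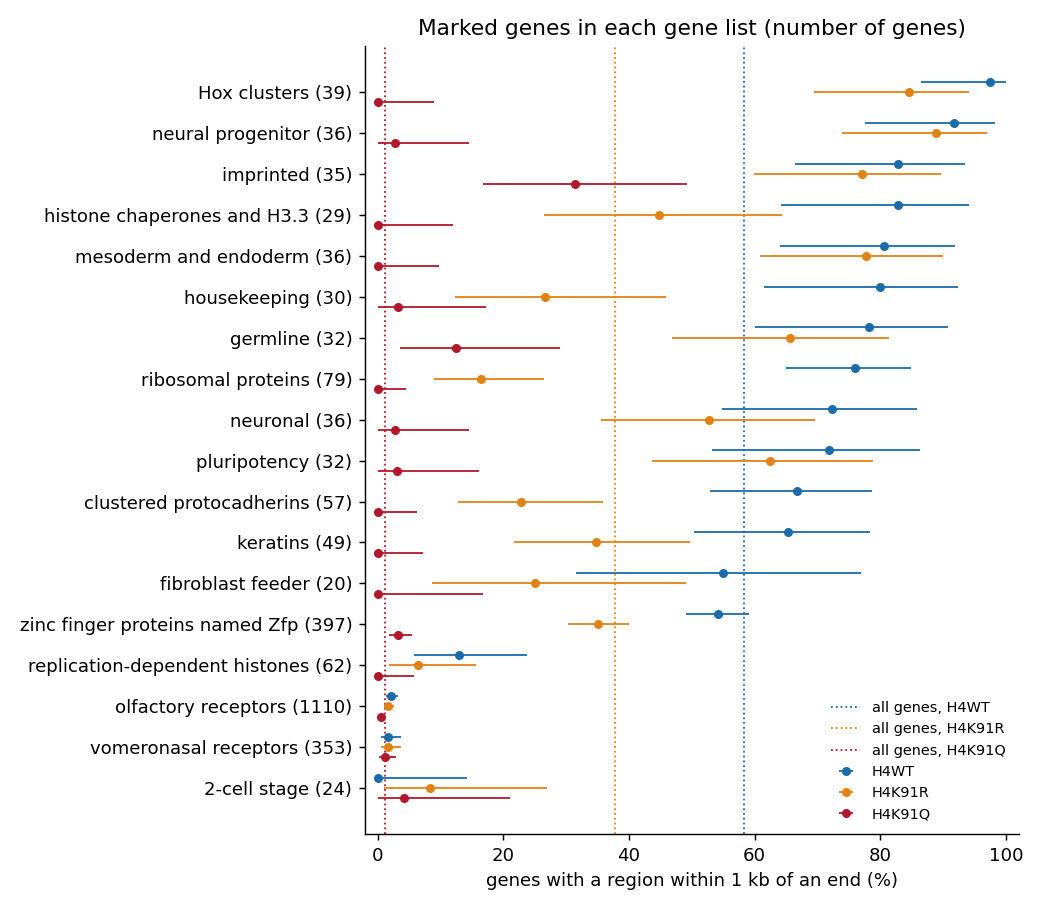
Percent of the protein-coding genes of each list (number of genes in brackets) with a region within 1 kb of an end (horizontal axis) for H4WT, H4K91R and H4K91Q, with exact 95% intervals as bars and dotted lines at the share of all protein-coding genes. Ribosomal protein genes were marked at 75.9% by H4WT and 16.5% by H4K91R, and imprinted genes at 31.4% by H4K91Q.

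Ribosomal protein genes had H4WT regions but few H4K91R regions. Of 79 ribosomal protein genes, H4WT marked 60 (75.9%, 65.0 to 84.9) and H4K91R 13 (16.5%, 9.1 to 26.5), and H4K91Q marked none. Among random lists, 0.08% held as many H4WT-marked genes, and 0% held as few H4K91R-marked genes (median 30). No H4K91Q-marked gene was held by 36.7% of random lists. Rps18, a protein of the small ribosomal subunit, was among the members of highest H4WT fold (region at chromosome 17, 33951156 to 33951541, fold 9.13) and also had an H4K91R region. Of the 60 H4WT-marked members H4K91R marked 13, against a median of 30 in random lists matched on H4WT fold. The H4WT list shortened until it marked as many genes as H4K91R held 24 ribosomal protein genes (H4K91R held 13), and lists of equal length held 14 and 1. The H4WT excess ended in these shorter lists: 24 is 30.4%, against 37.9% of all genes, and 14 is 17.7%, against 29.2%. Housekeeping genes were marked at 24 of 30 by H4WT and at 8 by H4K91R. Actg1 (an actin) and Cltc (the clathrin heavy chain) were among the members of highest H4WT fold. Of the 24, 8 had H4K91R, against a matched median of 12, with 5.34% of matched lists as low. The H4WT list shortened in the same way held 9 housekeeping genes (30.0%, against 37.9% of all genes), close to the 8 of H4K91R, so the H4WT excess ended here too. Actg1 was the 1 housekeeping gene with an H4K91Q region.

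Clustered protocadherins, adhesion genes of neurons, gave counts that depended on the window and on list length. H4WT marked 38 of 57 and H4K91R 13, 10 of them among the H4WT-marked genes against a matched median of 20, with 0.09% of matched lists as low. Pcdhb15, Pcdhb10 and Pcdhac1 had the highest H4WT folds, and Pcdha9, Pcdha8 and Pcdhb22 were marked by H4K91R and not by H4WT. The H4WT list shortened to mark as many genes as H4K91R held 11, and H4K91R marked 38 with windows of 2 kb. Counted over the whole gene and 1 kb, H4K91R lay at 48, against a length-matched median of 36, with 0.01% of lists as high. Members such as Pcdha8 and Pcdha9 overlap and share an end, so 1 region can count for several genes. Length-matched lists do not keep this, and no rotations were made for this whole-gene count, so no excess is read from it. H4K91Q marked no protocadherin end, as did 47.6% of random lists. In rotations of the gene order, which keep neighbours together, 43.5% held as many H4WT-marked genes and 19.6% as few H4K91R-marked genes. Keratin genes were marked at 32 of 49 by H4WT and 17 by H4K91R, histone chaperone and H3.3 genes at 24 of 29 and 13, and fibroblast genes, included because embryonic stem cells can be grown on feeder cells, at 11 of 20 and 5. H4K91Q marked none of these 3 groups, as did 53.8%, 69.7% and 77.2% of random lists of their sizes, in the same order. Krt7, Krt19 and Krt17 led the keratins, H3f3a (an H3.3 gene), Rbbp4 and Suv39h2 the chaperone group, and Col6a2, Fbn1 and Twist2 the fibroblast genes. Replication-dependent histone genes were seldom marked, at 8 of 62 by H4WT and 4 by H4K91R. These genes are short, and lists matched on length, counted over the whole gene and 1 kb, had a median of 11 H4WT-marked genes, with 13.9% as low as 8. For H4K91R the median was 8, with 5.58% as low as 4. Rotations of the gene order, counted at the ends and not matched on length, held as few in 1.61% for H4WT and 1.82% for H4K91R. H4c4, H1f2 and H1f4 had the highest H4WT folds.

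Of the 18 gene lists, imprinted genes had the largest share marked by H4K91Q. Of 35 protein-coding members, H4K91Q marked 11 (31.4%, 16.9 to 49.3), and 0% of random lists and 0% of rotations held as many. H4WT marked 29 and H4K91R 27. The 11 were Nap1l5, Peg3, Usp29, Plagl1, Nnat, Peg10, Sgce, Zrsr1, Mcts2, Igf2 and Cdh15. Nap1l5 had the highest H4K91Q fold (chromosome 6, 58906310 to 58907403, fold 13.6). The region of Peg3 and Usp29, a shared promoter, spanned chromosome 7, 6727842 to 6730971, with a fold of 11.6, and that of Peg10 and Sgce chromosome 6, 4747032 to 4748384, with a fold of 7.64. All 11 genes also had H4WT and H4K91R regions. Of the 8 non-coding imprinted genes, H4K91Q marked 5: Peg13, Airn, Gnasas1, H19 and Kcnq1ot1. The region at the low-coordinate end of Airn, the antisense RNA of Igf2r, lay at chromosome 17, 12741186 to 12743377, with a fold of 9.60.

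Germline genes and zinc finger genes had smaller H4K91Q excesses. Of 32 germline genes, H4WT marked 25, H4K91R 21 and H4K91Q 4, with 0.06% of random lists holding as many as 4. The 4 were Dpep3, Dazl (an RNA-binding protein of germ cells), Zp3 (an egg coat glycoprotein) and Mael (a piRNA pathway protein). Genes named Zfp were marked at 215 of 397 by H4WT, 139 by H4K91R and 13 by H4K91Q, with 0.21% of random lists holding as many as 13. Among them H4K91Q regions lay at Zfp605, Zfp160, Zfp33b and Zfp992 on chromosomes 5, 17, 5 and 4. Zfp808 and Zfp455 had an H4K91Q region and no region of the other tagged histones. Zfp787, Zfp385a and Zfp579 led the group for H4WT.

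Chemosensory receptor genes and genes of the 2-cell stage were seldom marked by H4WT and H4K91R. Of 1110 olfactory receptor genes H4WT marked 24, H4K91R 19 and H4K91Q 7, and of 353 vomeronasal receptor genes 6, 6 and 4. Random lists had medians of 648, 420 and 14 for the former and 206, 134 and 4 for the latter. These genes are short. Counted over the whole gene and 1 kb, H4WT lay at 27 and 15, against length-matched medians of 239 and 137. H4K91Q lay at 10 and 11, against 14 and 10, with 14.8% and 67.0% of lists as low. Olfr1349 had the highest H4WT fold among olfactory receptors, and Olfr113 and Olfr1341 had H4K91Q regions without H4WT. Vmn2r29, Vmn2r2, Vmn1r56 and Vmn1r65 were the 4 vomeronasal genes marked by H4K91Q, and each had H4WT and H4K91R regions too. Of the 6 H4WT-marked vomeronasal genes H4K91Q thus marked 4. Lists matched on H4WT fold had a median of 0, with 0% as high, although 6 genes are few. Of 24 genes of the 2-cell stage, H4WT marked none (random median 14). H4K91R marked Zfp352 and Tcstv3 (random median 9), but the scarcity of H4K91R ended in shorter lists, where the interval of 1.03 to 27.0% held the share of all genes. H4K91Q marked Tcstv3 (chromosome 13, 120318474 to 120318676, fold 3.78). Unique mapping of reads at the receptor and 2-cell stage genes was not tested, and random lists were not matched on it. A missing region there need not mean a missing histone. Empty-vector regions lay at 7 Zfp genes, 4 olfactory receptor genes, 2 neuronal genes, 2 keratin genes and 1 gene each of the Hox, germline and mesoderm and endoderm lists.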

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

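The comparisons above used protein-coding genes. Non-coding genes and pseudogenes were outside them, and in each class more of them had an H4WT or H4K91R region within 1 kb of an end than had an empty-vector region, with exact intervals that did not overlap. The same was so for H4K91Q at long non-coding RNA genes, pseudogenes and small nuclear RNA genes. At transfer RNA genes the interval of H4K91Q (0.268 to 2.49%) overlapped that of the empty vector. At microRNA and small nucleolar RNA genes the H4K91Q share was slightly below the empty-vector share, with overlapping intervals. For microRNA genes they were 0.685 to 2.01% and 0.871 to 2.31%. The H4WT, H4K91R and H4K91Q lists hold 23.0, 16.3 and 4.76 times as many regions as the empty-vector list, which by itself raises these shares, and no chance level was computed. The count was chosen after the main results were seen, and ends shared with protein-coding genes were not separated.

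Long non-coding RNA genes were marked at 25.2% by H4WT, 17.2% by H4K91R and 2.04% by H4K91Q, against 0.715% for the empty vector (12727 genes). Pseudogenes were marked at 8.53%, 6.28% and 2.11%, against 0.553% (9944 genes). Both classes had a larger share marked by H4K91Q than the 1.27% of protein-coding genes. MicroRNA genes were marked at 30.0% by H4WT and 18.6% by H4K91R, against 1.47% (1228 genes), and H4K91Q marked 1.22% of them. Transfer RNA genes were marked at 17.4% by H4WT, 7.11% by H4K91R and 0.980% by H4K91Q, with 0 of 408 for the empty vector (exact upper bound 0.900%). Small nucleolar RNA genes were marked at 9.18%, 4.33% and 0.672%, against 0.746% (1340 genes). Small nuclear RNA genes were marked at 4.68%, 2.29% and 0.896% by H4WT, H4K91R and H4K91Q, with 0 of 1004 for the empty vector (exact upper bound 0.367%).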

How the results depend on the processing

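The comparisons with all annotated genes, with the whole gene as window and with H4WT lists shortened to match H4K91R were chosen after the data were seen, and the other settings before the data were examined. In 101 recalculations of 25 main results, 67 moved and 34 stayed within the exact interval (counts within 1.5 times, rho within 0.1). Of the 34, 8 rest on identical peaks and could not move. The gap in H4K91R sharing closed at equal length, where about as many regions met H4K91Q as H4WT. The causes of these moves were not tested. Of 366 recalculations of list counts and ratios to chance, 270 stayed and 96 moved. With 1 library per group no library could be left out, and unknown depth limits all comparisons of list length. The planned sequence-composition results, with their equal-length and 1 kb alternatives, were not run. No paired analysis was possible because each group has 1 library and no test was made.

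Only peaks with a −log10 q of 5 or more left 853 empty-vector and 26265 H4K91R regions. Overlap with the empty vector was then 3.62% for H4WT and 3.14% for H4K91R. H4WT shared 29.6% with H4K91R, H4K91R 55.1% with H4WT and 20.4% with H4K91Q, and H4K91Q 49.5% with H4K91R and 17.7% with H4WT. Gene ends held 29.5% of H4WT and 21.6% of H4K91R regions, outside genes lay 21.7% and 39.1%, and 53.6%, 24.8% and 1.01% of genes were marked by H4WT, H4K91R and H4K91Q.

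Equal-length lists gave an overlap with the empty vector of 5.55% for H4WT and 3.77% for H4K91R. H4WT shared 32.6% with H4K91R and 6.95% with H4K91Q, H4K91R 32.5% with H4WT and 34.0% with H4K91Q, and H4K91Q 6.92% with H4WT and 35.1% with H4K91R. Gene ends held 43.6% of H4WT regions, outside genes lay 13.8% of H4WT and 43.0% of H4K91R regions, and 29.2% and 13.9% of genes were marked.

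An overlap of 50% of each region gave 1.42%, 1.14% and 0.224% with the empty vector for H4WT, H4K91R and H4K91Q. H4WT then shared 23.3% with H4K91R and 2.27% with H4K91Q, H4K91R 32.7% with H4WT and 9.83% with H4K91Q, and H4K91Q 10.7% with H4WT and 33.1% with H4K91R. With empty-vector regions kept, H4WT shared 38.5% with H4K91R, H4K91R 55.2% with H4WT, and 24.9% of H4WT regions were at gene ends.

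In the order H4WT, H4K91R, H4K91Q, windows of 500 bp placed 17.9%, 13.6% and 1.32% of regions at gene ends and marked 53.7%, 31.8% and 0.923% of genes, with 26.2% of H4WT and 38.6% of H4K91R regions outside. Windows of 2 kb placed 33.7%, 27.4% and 4.10% at gene ends and 24.1%, 36.7% and 75.2% outside, and marked 62.5%, 43.7% and 2.03% of genes. The whole gene and 1 kb marked 68.2%, 52.8% and 7.26%. With all annotated genes, 31.0%, 25.6% and 6.67% of regions were at gene ends and 18.7%, 30.4% and 65.1% outside.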

Other observations

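The tests on where H4K91Q regions lie, on short genes and on strong H4WT regions were chosen after the results they bear on were seen, as were the position, window and gene-body counts.

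H4K91Q regions lay more often than randomly placed ones near the low-coordinate ends of chromosomes, where the centromeres of mouse chromosomes are, although most lay elsewhere. The first 20 Mb of each chromosome held 22.7% of H4K91Q regions (22.0 to 23.4), 13.0% of H4K91R regions and 9.44% of H4WT regions, against about 14.7% of randomly placed H4K91Q regions. In lists of equal length the shares were 14.9% for H4K91R and 9.64% for H4WT. Placed at random in windows of the same gene number, H4K91Q regions were there in 13.9% on average and at most 14.4% over 100 placements. The 1 Mb window with the most H4K91Q regions, 59, was chromosome 13 from 62000001 to 63000000, which holds Zfp808, Zfp935 and Zfp934. Next came chromosome 1 from 7000001 to 8000000, with 57 regions and 1 protein-coding gene, Pcmtd1. Of the 10 richest windows, 7 held no Zfp gene and 1, chromosome 4 from 147000001 to 148000000, held 9. The windows had a median of 10.5 protein-coding genes, against 44 for the richest H4WT and 34.5 for the richest H4K91R windows. Counted over the whole gene and 1 kb, H4K91Q regions lay at 53 of 397 Zfp genes. Lists matched on gene length had a median of 25, and rotations of the gene order had a median of 28 and at most 51. H4WT regions lay at 266 Zfp genes and H4K91R regions at 209 by the same count. Chromosome 10 from 80000001 to 81000000 (54 genes, among them Stk11 and Gpx4) held 477 H4WT and 230 H4K91R regions. Chromosome 8 from 120000001 to 121000000, with Irf8 and Gse1 among its 11 genes, held 380 and 242.

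The place of H4K91Q regions, 76.2% outside genes, was weighed against technical explanations. Shortening the H4WT list did not give such a share: at equal length 13.8% of its regions lay outside genes. This could be foreseen, since 15.1% lay outside in the H4WT group of highest fold and 32.4% in the group of lowest fold. The value describes the shortened list and is no independent test of list length. Background of the anti-HA pulldown would need empty-vector regions to lie outside genes as often, and 31.6% did. Read pileups that every library shares could appear in the other tagged lists too. The H4WT list held 18.8% of H4K91Q regions, but the H4K91R list held 53.5%, and 78.1% of those in the group of highest fold. Regions overlapping the empty vector had been removed before. Each list was called alone at unknown depth, so a shared pileup can be missing from a list. These shares therefore cannot decide on shared pileups, which stay open. Mapping of repeated DNA in ways that differ between libraries was not tested and stays open. A difference between single libraries other than the genotype cannot be told apart from the substitution, since each has 1 library. The separately made H4K91R library had 43.0% outside genes at equal length, which cannot decide between them for the same reason.

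The scarcity of H4K91R at ribosomal protein genes, 13 of 60 H4WT-marked members, was larger than a shorter list that loses the weaker H4WT regions first would give. In lists matched on H4WT fold the 2.5th percentile was 23 genes. Short genes were also no sufficient cause: 0% of 10000 lists matched on gene length held as few H4K91R genes. Transcription and CpG content of these genes were not tested, and a difference between the single libraries stays open. No biological explanation was tested.

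The H4K91Q regions at 11 of 35 imprinted genes were not matched by neighbouring genes counted as separate members, with 0% of rotations of the gene order holding as many. Long genes also did not account for them, with 22 genes counted over the whole gene and 0% of length-matched lists holding as many. Nor did strong H4WT regions, since lists matched on H4WT fold reached 3 genes at the upper end of their middle 95%. The highest H4K91Q region of each gene overlapped the highest H4K91R region at all 11 genes and the highest H4WT region at 10, Cdh15 being the exception. Sequence content, mapping of repeated DNA and a difference between single libraries were not tested and stay open, and no biological explanation was tested.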
